A study of Homo sapiens with 6 samples.

How the data were processed

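Total RNA of 6 cultures of hFOB 1.19, a human fetal osteoblast line, was depleted of ribosomal RNA and sequenced with a strand-specific kit for 150 cycles, per the labels' protocols. Of these, 3 were exposed to Staphylococcus aureus at a ratio of 1:25 for 2 h at 37 °C and then to gentamicin at 100 µg/mL for 1 h, and 3 received buffer. Groups and replicate numbers were taken from the labels, and the columns of the tables were matched to the libraries by name. The labels do not say whether the cultures were grown independently, so p-values of tests between the groups measure only the spread between these libraries.

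The authors deposited 2 tables of circular RNAs (circRNAs), 117 listed as higher and 125 listed as lower in infected cells. Each table holds counts of back-splice junction reads per library, which the authors deposited as whole numbers. It also holds log2 CPM values made with edgeR, per the file headers. The authors' deposited p-values and false discovery rates (FDR) come from their own test. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks, Cuffdiff and genome build hg19. The tool that called back-splice junctions is not given in the sources used here. Coordinates are those of the deposited tables, on hg19. Circular RNAs outside the 2 tables were not used here, so every tested circRNA had been selected by the authors on these same libraries, and a test of it is not independent evidence.

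The log2 CPM of each circRNA is a fixed function of its reads, an effective library size and a prior count, so the effective sizes were solved from the deposited values with a prior count of 2. The largest misfit was 5.15e-14 over the 5 libraries with listed reads. Infected replicate 1 had none, so its size is what the mean over 6 libraries leaves after the others. The size of infected replicate 1 thus rests on the prior count being exactly 2, and the misfit does not cover it. On simulated counts the sizes came back with an error of at most 2.74e-12%. An effective size includes the normalization factor and is not the raw number of junction reads. In the simulation an almost empty library of 34 reads had an effective size of 774 with TMM factors, 22.8 times its raw total, so limits set from the effective size of infected replicate 1 can be far off. Rates are junction reads per 10000 effective reads. Intervals are exact Poisson 95% intervals, and a count of 0 was taken to allow up to 3 reads; both cover counting error only. A ratio between groups was taken over pooled reads, with an exact interval that also covers counting error only and not the spread between libraries. Against a group with no reads the ratio is a bound set at 3 reads over that group. The bound takes the reads of the other group as exact, so "at least" is not a 95% limit on the ratio. No pair among the 15 pairs of libraries held identical reads.

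Counts were tested with edgeR 4.0.16 (glmQLFit, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over 242 circRNAs at 0.05, and with the column sum over both tables as library size. Infected replicate 1 had a column sum of 0, which gives that library no weight, so this fit rested on 5 libraries (2 infected and 3 uninfected). DESeq2 1.42.0 was the other tool. The test was checked on counts simulated at the recovered effective sizes of these libraries. There uninfected replicates 1 and 2 stood at 4844 and 13181, while the fit to the deposited reads entered them at 83 and 821. The simulation is thus no check of that scaling. At a dispersion of 1.32, close to the fitted value, it called 0% of 98 circRNAs changed 8-fold and 1% of 100 changed 32-fold; at 0.4 it called 40% and 83%. Classes, chromosomes and host gene lists were compared between the 2 tables by two-sided Fisher's exact tests, lengths by a permutation test of medians with 100000 resamples, and hosts in both tables by 10000 reassignments of the labels (Python 3.11.15, scipy 1.17.1). These comparisons take circRNAs as units and do not measure spread between libraries. Circles of the same host gene are not independent.

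The comparisons, the 13 host gene lists and the rule for named circRNAs were fixed before the data were examined. The rule takes, per direction, the 8 circRNAs with the smallest p and the 4 with the highest level, up to 4 per host gene list, up to 4 hosts in both tables, up to 3 hosts with the most circRNAs, and up to 4 per direction detected in one group only. Some circRNAs that the rule takes are not reported here. Of 222 host names, 209 matched a current or older symbol. Alternatives were a replicate block, TMM factors, equal library sizes, DESeq2, a detection filter, another prior count and each library left out. Recovered effective sizes as library sizes were added after seeing the data.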

Results

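Back-splice junction reads of circRNAs were compared between 3 infected and 3 uninfected libraries of hFOB 1.19 osteoblasts, asking which circRNAs differ after exposure to Staphylococcus aureus. The 242 listed circRNAs came from 222 host genes. Infected replicate 1 held no read of any of them, and its recovered effective size was 47.1 reads. The other infected libraries had effective sizes of 13638 and 10736, and the uninfected ones 4844, 13181 and 9651. A count of 0 in infected replicate 1 allows a listed share of up to 6.37% if its effective size is taken as its depth, while infected replicates 2 and 3 held 5.64% and 5.94%. A lower level of these circRNAs in that library was therefore not detectable at this depth, and means below are over 2 infected and 3 uninfected libraries.

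**Figure D1:**
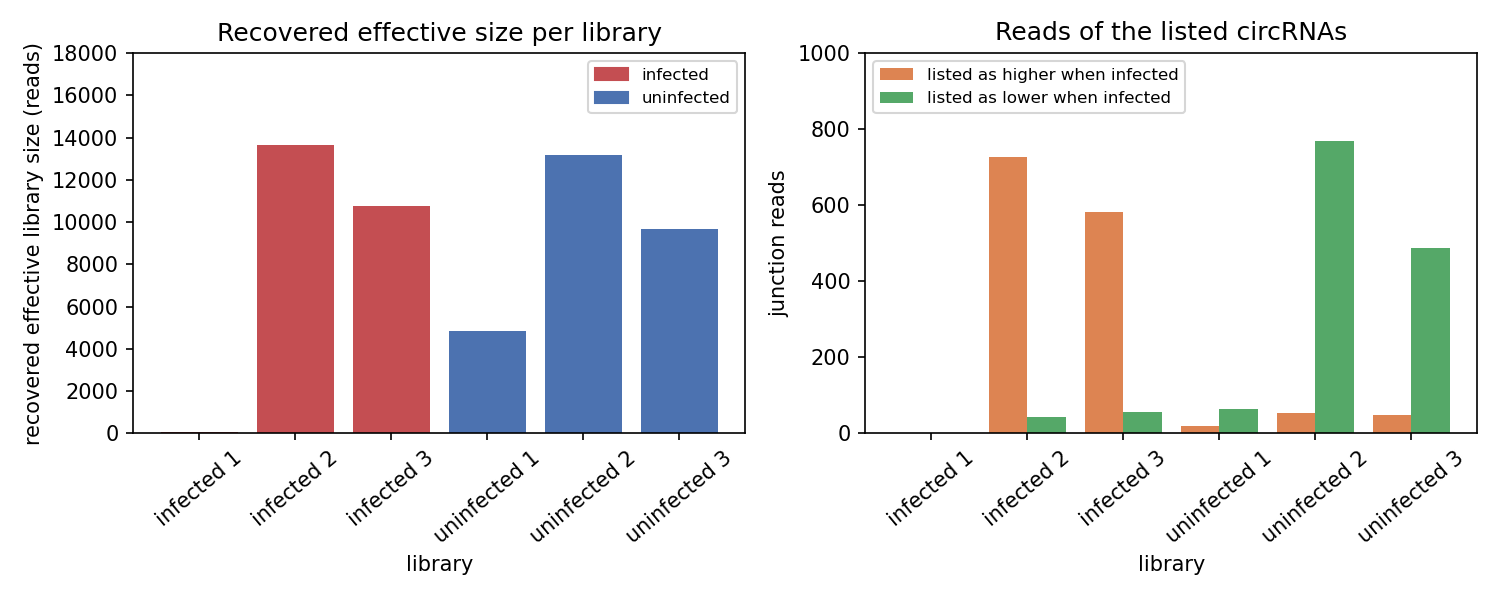
Recovered effective size of each library in reads (left; red infected, blue uninfected) and junction reads of the circRNAs listed as higher or as lower (right), 1 bar per library and list. Infected replicate 1 has 0 listed reads, and uninfected replicate 1 has 83 in all.

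By edgeR p-value, the listed circRNAs that ranked first were circles of PAPPA, a secreted metalloproteinase, and KMT2C, a histone methyltransferase, on the higher side, and of SLC8A1, a sodium-calcium exchanger, RPRD1A and ATXN2 on the lower side. The PAPPA circle (hsa_circ_0002052, exonic, chromosome 9, 118969735 to 118997916) had 23 and 8 reads in infected replicates 2 and 3 and 0, 2 and 1 in the uninfected libraries, a pooled ratio of 11.7 (95% interval 3.66 to 60.0), and 6.87 without infected replicate 2. The SLC8A1 circle (hsa_circ_0005232, exonic, chromosome 2, 40655613 to 40657441) had 0 infected reads and 3, 2 and 13 uninfected reads, at least 5.28-fold lower in infected cells, and at least 2.25-fold without uninfected replicate 3. Intervals of pooled ratios cover counting error only and not the spread between libraries, and this PAPPA circle had an edgeR adjusted p of 0.191. None of the 242 passed the edgeR test at an adjusted p of 0.05. The smallest adjusted p was 0.118, 54 were under an unadjusted p of 0.05 (15 higher and 39 lower), and DESeq2 called 13, all lower, with 178 adjusted p-values not given. Leaving out 1 library moved the 54 to 14 (infected replicate 2), 31 (infected replicate 3), 13 (uninfected replicate 2) or 9 (uninfected replicate 3), and TMM factors gave 15 higher and 3 lower. With listed reads as library size, uninfected replicate 1 entered the edgeR fit at 83 reads and uninfected replicate 2 at 821. Their effective sizes, on which the ratios rest, were 4844 and 13181. With recovered effective sizes over 5 libraries, 20 higher and 11 lower were under an unadjusted edgeR p of 0.05. The lean of the 54 to the lower side thus depends on the scale. In the authors' deposited table all 242 share an FDR of 0.793, with p-values from 0.00108 to 0.0476.

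KMT2C (hsa_circ_0006784, exonic, chromosome 7, 151960101 to 152012423) had 6 and 13 infected reads against 1 uninfected read, a ratio of 21.6 (3.43 to 896). The ratio was 33.5 without infected replicate 2, 12.2 without infected replicate 3 and 11.3 without uninfected replicate 2. Without uninfected replicate 3, which held the uninfected read, only a bound of 4.68 was left. Circles of FOXO3 (a forkhead transcription factor), GPATCH2L and TRPM7 (a cation channel) each had 5 and 2 infected reads and none in uninfected cells. Circles of UBAP2 (hsa_circ_0138666), CTBP1 (hsa_circ_0007149) and BARD1 (hsa_circ_0119087), hosts that each have another listed circle, had 4 and 3. By the bound at 3 reads, each of these 6 was at least 2.65-fold higher. That bound was 1.39 without uninfected replicate 2, and none could be given without infected replicate 2. Circles of NAV2, EDC3, RASA2 and RHBDD1 had the same reads as the last 3 and were left out by their order alone. On the lower side RPRD1A (hsa_circ_0000842, chromosome 18, 33606863 to 33613800) had 7, 6 and 2 uninfected reads and ATXN2 (hsa_circ_0002457, chromosome 12, 111990084 to 111993723) had 2, 5 and 7, at least 4.40-fold and 4.11-fold lower in infected cells. STX6, a syntaxin of vesicle traffic, had 1, 5 and 8, MAP3K4 had 3 in each uninfected library, and FAM73A had 3, 9 and 0. KIAA0368 had 3, 2 and 16 uninfected reads and 1 infected read, a ratio of 18.5 (2.97 to 765), and 6.76 without uninfected replicate 3. ZMIZ1 rested on 7 reads of uninfected replicate 2. For each of the 16 circRNAs with the smallest p in either list, the ratio or bound moved by over 1.5 times with some library left out, and for 8 of them no fold could then be given. RPRD1A alone passed 0.05 when uninfected replicate 2 was left out (edgeR adjusted p = 0.0430), and without uninfected replicate 1, which holds 7 of its 15 reads, its fitted log2 fold change went from -2.95 to -1.55 (adjusted p = 0.223). Its adjusted p ranged from 0.0198 (DESeq2) to 0.229 (equal library sizes) over the alternatives.

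**Figure D2:**
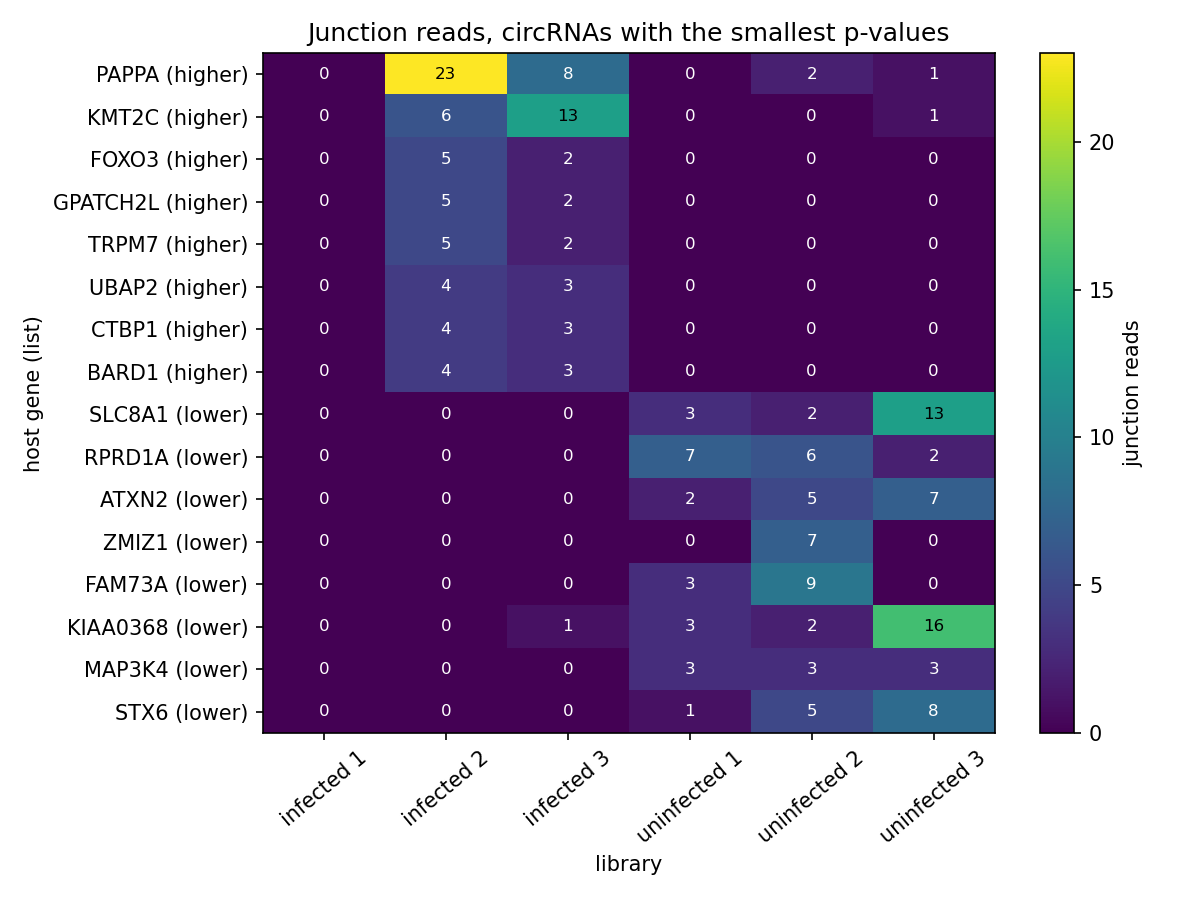
Junction reads per library (columns) for the 8 circRNAs with the smallest p in each list (rows, host gene and list). Colour and printed number give reads. Circles of NAV2, EDC3, RASA2 and RHBDD1, with the same reads as UBAP2, CTBP1 and BARD1, are not shown. PAPPA reaches 23 reads in infected replicate 2, and every value of infected replicate 1 is 0.

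The most abundant listed circRNAs had reads in both groups. Among those listed as higher, THSD1 (hsa_circ_0008776) had 16.4 ± 9.72 reads per 10000 (SD, n = 2) in infected cells and 3.59 ± 1.33 (SD, n = 3) in uninfected cells. PHKB, a phosphorylase kinase subunit, had 15.1 ± 5.58 against 3.93 ± 0.742, MED13L 14.2 ± 1.67 against 4.12 ± 2.76, and CRKL, an adaptor protein, 14.2 ± 1.67 against 5.54 ± 3.19, on the same scale. Among those listed as lower, ASAP1 (hsa_circ_0008934) had 4.36 ± 3.05 against 12.8 ± 4.65, NBPF1 3.13 ± 1.79 against 11.2 ± 7.09, SRSF4, a splicing factor, 2.33 ± 3.29 against 9.65 ± 3.90, and ATXN1 3.40 ± 3.49 against 8.16 ± 5.62. The edgeR adjusted p was 0.205 for THSD1, 0.283 for PHKB, 0.291 for MED13L and 0.536 for CRKL. It was 0.191 for ASAP1, NBPF1 and SRSF4 and 0.221 for ATXN1. The pooled ratio of the higher over the lower group moved by over 1.5 times with some library left out, except for PHKB. It ranged from 2.40 to 5.86 for THSD1 (3.92 in full) and from 1.85 to 4.16 for CRKL (2.48). For ASAP1 it ranged from 1.88 to 5.58 (2.99 in full), and for ATXN1 from 1.20 to 8.53 (2.15).

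Detection was sparse. Of 242 circRNAs, 89 had reads in 1 library, 82 in 2 and 10 in 5. Among those listed as higher, 55 of 117 had reads in 1 infected library and 89 had none in uninfected cells. Among those listed as lower, 90 of 125 had none in infected cells. Detection in at least 2 libraries of one group and none of the other held for 38 circRNAs of infected and 52 of uninfected cells, 90 in all. The numbers were 41 and 12 without uninfected replicate 2, 42 and 13 without uninfected replicate 3, and 0 and 62 or 0 and 68 without infected replicate 2 or 3, which leaves no pair of infected libraries with reads. Ranked by mean rate and not by reads, those of infected cells were led by RPS6KC1 (10 and 4 reads), APAF1, an apoptosome component (6 and 6), ESYT2 (7 and 5) and RBM23 (4 and 6). Those of uninfected cells were led by SLC8A1, RPRD1A, ATXN2 and STX6. Groups of 3 did not overlap for 17 circRNAs, all lower (13.6% of that list), where chance gives 5% in one direction for unselected circRNAs in libraries of like depth. Circles higher in infection could not qualify with infected replicate 1 at 0. That library could not break a separation on the lower side either. The 13.6% is thus in effect 2 infected libraries against 3, on unscaled reads, where chance gives 10% and not 5%. The 5 libraries with listed reads were also compared after scaling by effective size. Then 57 of those listed as higher (48.7%) and 21 of those listed as lower (16.8%) did not overlap. Chance gives 10% in one direction for unselected ones without ties in libraries of like depth. With or without scaling, a lower circRNA can qualify only with reads in all 3 uninfected libraries, which 23 of 125 had (18.4%). A higher one needs reads in infected replicates 2 and 3, which 62 of 117 had (53.0%). The shares of the 2 lists are thus limited by detection and cannot be compared.

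Circles from host genes of the matrix and osteoblast list, among them FN1 (fibronectin) and RUNX2 (an osteoblast transcription factor), numbered 3 in the higher table and 0 in the lower (Fisher's exact p = 0.112, adjusted 0.866). RUNX2 had 8 reads and FN1 10, all in infected replicate 2. The innate signalling list held TBK1, a kinase upstream of interferon, with 9 reads in infected replicate 2. Of the uptake and actin list 3 were higher and 6 lower, the latter with MYO10 (1 infected and 17 uninfected reads), SEPT9 (1 and 13), UTRN (0 and 8) and a PTK2 circle (hsa_circ_0002483, 1 and 16). The apoptosis list held APAF1 on the higher side and 3 circles of BIRC6 on the lower side. The ubiquitin list had 3 higher, among them ITCH (8 reads in infected replicate 2) and USP3 (7 in infected replicate 3). Its 3 lower were the same 3 circles of BIRC6. The chromatin list had 4 higher and 2 lower, with KMT2C, KMT2E and HDAC9 against SMARCC1, and RNA processing had 5 and 7, with TNRC6B, NUP98, XPO1 and SRSF4 lower. The cell cycle and repair list had 4 higher and 7 lower, with BARD1 (2 circles) higher and AURKA, MSH3 and KIF15 lower. The mitochondrial and metabolic list of 65 genes had 0 higher and 2 lower, with ACACA lower (7 and 3 reads in uninfected replicates 2 and 3, none in infected cells). Listed circles from hosts of abundant circRNAs known from other cells numbered 7 and 6, including FOXO3, SLC8A1 and KIAA0368. The autophagy list of 58 genes and the leukocyte and other-cell marker lists held none. A list is a choice of genes, so hosts of the same process may lie outside it. No list passed the test between the tables, the smallest adjusted p being 0.866. Adjusted over the list alone, 2 circRNAs of the abundant hosts passed edgeR and none of any other list; the authors chose these circRNAs on the same libraries.

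Of 17 host genes with several listed circRNAs, 8 had circles in both tables, where random labels gave 9.15 on average (95% range 5 to 13). PTK2, the focal adhesion kinase, had 7 and 2 infected reads of one circle (hsa_circ_0085769) with none in uninfected cells, and 16 uninfected reads of another (hsa_circ_0002483) with 1 infected. PAPPA and UBAP2 also had one of each. FNDC3B had 4 listed circles, 2 higher and 2 lower. BIRC6, an inhibitor of apoptosis, had 3, all lower, which share a boundary at position 32602656 of chromosome 2.

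Lengths are predicted ones, and outside the exonic class they can equal the whole genomic span (68200 bases for the BARD1 circle hsa_circ_0119087). The median predicted length was 658 bases for 117 circles listed as higher and 815 for 125 listed as lower (two-sided permutation p = 0.0398). But the difference in mean log2 length did not pass (permutation p = 0.162). Among exonic ones the medians were 598 and 719, which did not pass either (permutation p = 0.0673). Exonic circles made up 84.6% of the higher and 82.4% of the lower table, and no class (smallest adjusted p = 0.973) and none of 24 chromosomes passed the test between tables.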

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

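The recovered effective sizes, and what was computed with them, were chosen only after the data were seen. No edgeR setting on all 5 or 6 libraries gave an adjusted p under 0.05, whereas DESeq2 called 13, all lower; leaving out each library gave 0 to 1, the 1 (RPRD1A) without uninfected replicate 2. Without infected replicate 2 or 3 a single infected library remained, which is assumed to vary like the others, and leaving out infected replicate 1 moved nothing since it had no weight. The count at an unadjusted p under 0.05 moved from 54 (15 higher, 39 lower) to 18 with TMM factors (15 and 3), 6 with equal sizes over 6 libraries (1 and 5), which also brings in infected replicate 1, 24 of 71 with the filter, 30 with DESeq2 (0 and 30), 31 with recovered sizes over 5 libraries (20 and 11), 99 over 6 (80 and 19) and 88 with the block added. Over the same 5 libraries the split into higher and lower thus depends on the scaling. TMM factors moved the median log2 fold change by 0.26 and recovered sizes over 6 libraries by 0.14, in a median over lists that go both ways. DESeq2 moved it by -1.44, and a prior count of 0.5, which leaves the scaling as it was, by -0.54. Without uninfected replicates 2 or 3 it moved by 1.68 or 1.48, where circRNAs with no reads left dropped out (220 and 226 tested). The replicate block gave 0 calls and 91 at p under 0.05 (41 and 50); whether replicate numbers pair the libraries could not be tested, since deviations of 2 infected libraries are opposite by construction. Non-overlapping circRNAs numbered 74 with column sums and 78 with recovered sizes over 5 libraries, against 17. Detection in one group only was 12 against 90 when all 3 libraries were required, which no infected-only circRNA could meet, and ranged from 53 to 90 with a library left out. The length difference was -121 bases in exonic circles and -0.29 in mean log2 length (permutation p = 0.0673 and 0.162), both past no threshold. Hosts in both tables numbered 0 among circRNAs non-overlapping over 6 libraries and 2 over 5, with fewer circRNAs entering. A FNDC3B circle (hsa_circ_0006156) had a log2 fold change of 0.87, and of -0.44 to 1.61 with a library left out, reversed without infected replicate 2. Beyond these constructions the cause was not tested. Classes and host lists among circRNAs past the threshold could not be run, as none passed in edgeR on the 5 libraries.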

Other observations

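Apart from the count of splits, the tests in this part were chosen after the results were seen. What each test would show, the splits included, was written down only after it had been run.

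Infected replicate 1 had no listed read. At the listed share of infected replicates 2 and 3, 2.72 reads would be expected in a library of its effective size (a share taken from circRNAs selected in those libraries), and the Poisson chance of 0 is 0.0659, so too few junction reads may account for it. The effective size is not the raw total; in a simulated almost empty library it was 22.8 times the raw total, and with fewer reads than assumed a count of 0 would be more probable. A loss of circRNAs upon infection stays open: the smaller effective size of infected replicates 2 and 3 was 10736, against 4844 to 13181 in uninfected libraries, but effective sizes do not measure circRNA abundance without the total sequencing depth, which was not used here.

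Many circRNAs were listed on the reads of 1 library of a group: 55 listed as higher had all infected reads in 1 library, where a split by effective size alone gives 0.964, and 39 listed as lower had all reads of uninfected replicates 2 and 3 in one of them, where it gives 1.85. The upper limits of that split were 3 for those listed as higher and 5 for those listed as lower. Both counts lie above these limits. For these circRNAs, which the authors selected, they argue against counting error around 1 level per group as the only source. Whether the further spread lies between cultures was not tested. An almost empty library counted as a replicate may lower p-values: in simulated unchanged circRNAs it added 2.83 percentage points to the share reaching 0.05 at a dispersion of 0.4 and 7.70 at 1.5. With recovered sizes, 30 of the 89 circRNAs with reads in 1 library, all listed as higher, reached an unadjusted 0.05 in edgeR with that library in the fit and 0 without it. With column sums, where that library has no weight, 10 of the 89 did in the main fit, all listed as lower and ZMIZ1 among them. With the replicate block 47 did (24 higher and 23 lower), and with TMM factors 3, all higher. The almost empty library is thus not needed for a small p-value, and its part in the authors' listing stays open.

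A hypothesis is that uninfected replicate 1, the shallowest usable library, leans to the table listed as lower. Its mean rate per circRNA was 1.07 for the lower table and 0.318 for the higher (two-sided permutation p = 0.00492), while 24 and 12 circRNAs had a read there (Fisher's exact p = 0.0698). Its level was not that of the other uninfected libraries: the lower table had 134 reads per 10000 (95% interval 104 to 171) against 583 (542 to 625) and 504 (460 to 550) in replicates 2 and 3. The 2 tests lie on different sides of 0.05, and because the authors chose the tables with this library included, a lean and that selection cannot be told apart.

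In the edgeR test, 10 of the 10 splits of the 5 libraries into 2 and 3 gave as many calls, since the real split gave 0 and the highest of the others 0. At an unadjusted p under 0.05 the real split gave 54 and the highest other 6, but the authors had listed these circRNAs for a small p on the real grouping, so this difference was set by the selection. With 10 splits no share under 0.05 can be reached.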
